A study of Mus musculus with 2 samples.

How the data were processed

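Single-cell RNA sequencing was done on cells of dysplastic mouse gastric organoids that had been kept with DMSO or with the drug pyrvinium, 1 library per treatment. Per the labels' protocols, cells were captured and lysed with the PIPseq method of Fluent BioSciences, and the libraries were made with its T2 kit. Per the submitters' processing notes, the software Partek and the mouse genome build GRCm39 were used. The aligner, the counting tool, the gene annotation and any filter on barcodes are not given in the sources used here. Each deposited matrix holds whole-number counts per gene and barcode that are not normalized, over 32227 genes. The barcode lists were not reduced to cells: they hold 331629 barcodes for DMSO and 353485 for pyrvinium, with 64212118 and 64412821 counts. Whether a count is a molecule or a read after removal of duplicates is not stated, so intervals cover counting error only.

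A barcode was kept as a cell when its total count was at least 1/10 of the 99th percentile of the top 2000 barcodes of its own library, it had at least 500 genes, and at most 20% of its counts came from mitochondrially encoded genes. This gave a threshold of 9320 counts in the DMSO library and 13100 in the pyrvinium library. The mitochondrial limit removed 0 further barcodes in either library. The counts per barcode declined without a sharp step, so the number of cells depends on the threshold, and fewer but deeper cells were kept from the pyrvinium library. Doublets were not removed in the main setting. Barcodes with 100 to 500 counts, 48316 for DMSO and 52143 for pyrvinium, were taken as a profile of free RNA. They held 19.9% and 23.6% of all counts.

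Counts of all kept cells were summed per library and scaled to counts per 1000000 (CPM) of that sum. Each gene was given an exact Poisson 95% interval and a log2 ratio of pyrvinium over DMSO with an exact conditional binomial 95% interval. A gene with 0 counts in a library was set against a floor of 3 counts. With 1 library per group no test was run, no p-value was computed and no difference has a replicate check. Cells were not treated as replicates. The computation was checked on simulated counts for 15596 genes with the depth of these sums. Both libraries were Poisson draws from the DMSO profile, so variation between cells or cultures was not simulated. Of the intervals, 95.7% held the true ratio. The 200 changed genes were taken from those with at least 20 CPM in the DMSO sum. Of them, 100% of those changed by each of 4 fold sizes (50 genes each) passed the size rule, as did 1.20% of the unchanged genes. Changed genes of lower expression were not simulated.

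A total of 36 gene lists covering pathways, cell types, the cell cycle, energy metabolism and sample quality were written before the data were examined. For each list, the median log2 ratio was taken over members with at least 20 counts in the libraries together, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members at least 1.5-fold higher or lower, with the whole counting interval on that side of 1, were counted. These describe the 2 libraries, not the treatments. In the features file 27 symbols are shared by several genes; the gene with the lowest Ensembl number was used under the symbol, as for Ddit3 and Aldoa, and 2 listed symbols were matched by their older names. The genes named are the 12 with the highest and the 12 with the lowest log2 ratio, ranked by the interval bound nearest 0 among genes with at least 20 CPM in a library, without mitochondrial, ribosomal protein and unnamed gene models; up to 4 members of each list described with the largest ratio and at least 10 CPM in a library; and a fixed set of stem cell, lineage and pathway genes. Some of the genes that these rules take are not reported here. The genes whose share of cells is given were chosen from these after their ratios were seen.

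Kept cells were clustered on 2000 variable genes, scaled to 10000 counts per cell, log-transformed and z-scored within each library, with 30 principal components, 15 nearest neighbours and the Leiden algorithm at resolution 0.5. Ratios within clusters were computed for clusters with at least 30 cells of each library. Shares of cells with a count were compared after each cell was thinned at random to 5000 counts, which every kept cell reached, so 0 cells were left out. Their intervals are exact binomial (Clopper-Pearson) 95% intervals. S and G2M calls compare the mean log value of each cell cycle list with that of genes of like expression.

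Alternatives fixed before the data were examined were thresholds of 1000 and 3000 counts, a mitochondrial limit of 10% or none, scaling without mitochondrial and ribosomal protein genes, scaling by the median of ratios over genes with at least 50 counts in each library, the mean over cells, removal of the 5% of cells with the highest Scrublet score, subtraction of 10% free RNA, equal cluster weights, another minimum for list members, other cluster settings and no thinning. Subtraction of free RNA from barcodes with 100 to 500 counts, and restriction to cells of the same range of counts, were added after seeing the data. Coordinates are not printed, because the annotation at hand (GENCODE M21) is on GRCm38, another build than that of the processing notes. It was used only for names, overlaps and a search of its transcripts for nuclear copies of mitochondrially encoded genes. A copy had to share at least 20 words of 31 bases with such a gene, and copies outside this annotation were not seen. Of the 138 named genes 137 were found in it, 26 with a gene overlapping on the same strand and 53 on the other strand. Counting by strand is not stated, so counts of these genes may include reads of the overlapping gene. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.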

Results

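The series followed Meta4 organoids, a dysplastic line grown from the mouse stomach corpus of animals with a Mist1-driven inducible Cre recombinase. Organoids received the solvent DMSO or pyrvinium, an anthelmintic drug, for 1 day, and the series asked which cell populations of the dysplastic organoids respond before their shape changes. Single-cell RNA sequencing gave 1 library per treatment, so no value below has a replicate check, intervals are 95% and cover counting error only, and "higher" or "lower" compares these 2 libraries. The DMSO library held 1602 kept cells with a median of 18593 counts and 3644 genes per cell, and the pyrvinium library 854 cells with 31517 counts and 4688 genes. Summed over cells, they gave 39980497 and 37046673 counts. Mitochondrially encoded genes took 2.57% of the DMSO sum and 1.63% of the pyrvinium sum, and ribosomal protein genes 25.3% and 29.9%.

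The pyrvinium library stood out from the DMSO library by high transcripts of the integrated stress response and low transcripts of the hypoxia response and of NF-kappaB targets. Ddit3 (ENSMUSG00000025408), which encodes the stress-induced transcription factor CHOP, was at 39.1 CPM (interval 37.2 to 41.1) with DMSO and 311 CPM (305 to 317) with pyrvinium, 7.96-fold higher. Gdf15 (ENSMUSG00000038508), a secreted stress cytokine, was at 98.7 and 742 CPM, 7.52-fold higher. Trib3, a pseudokinase induced by CHOP, was 4.76-fold higher, the cystine transporter gene Slc7a11 4.07-fold, Cth, a gene of cysteine synthesis, 5.10-fold and the stress gene Gadd45a 4.22-fold. The dual-specificity phosphatase gene Dusp4 was 7.92-fold higher (log2 ratio 2.99), but not throughout the library. With each cell thinned to 5000 counts, it was counted in 6.99% of DMSO and 34.0% of pyrvinium cells. In cluster 5, which held 254 of the 854 pyrvinium cells, the share was 5.12%. The other genes among the 12 highest were Ifi27, Hsd17b13, Kif13a, Slpi and Mettl18, with ratios between 4.22 and 10.1.

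Among the 12 lowest, Fosb, Fos and Egr1, each known as an immediate-early gene, were 47.6-fold, 13.7-fold and 10.8-fold lower with pyrvinium, and the phosphatase gene Dusp1 14.7-fold lower. Fos (ENSMUSG00000021250) was at 491 CPM (484 to 498) with DMSO and 35.9 CPM (34.0 to 37.9) with pyrvinium. The lactate exporter gene Slc16a3 was 17.8-fold lower, Ankrd37 25.1-fold and the mitophagy receptor gene Bnip3 8.64-fold, from 419 to 48.5 CPM. Tafa2, AA467197, Rnf186 and Pthlh, a gene of a parathyroid hormone-like peptide, were also among the 12, at 33.9-fold, 28.0-fold, 9.94-fold and 6.70-fold lower. Tafa2 was more abundant among barcodes with 100 to 500 counts (115 CPM with DMSO) than in cells (32.9 CPM), so its level in cells is uncertain. The size of these low ratios depends on the free RNA profile subtracted and on its share, which was not measured. With 10% subtracted in the profile of barcodes with 10 to 100 counts, the log2 ratio went from -5.57 to -9.35 for Fosb, from -4.65 to -8.74 for Ankrd37 and from -3.88 to -5.99 for Dusp1. It went from -3.78 to -4.59 for Fos, from -3.43 to -4.52 for Egr1 and from -3.11 to -3.72 for Bnip3. In the same setting AA467197 went from -4.81 to -6.60, Tafa2 from -5.08 to -6.72 and Pthlh from -2.75 to -3.45, and the log2 ratio of Rnf186 moved by -0.69. This profile rests on only 227188 DMSO and 274027 pyrvinium counts, and a gene left with 0 took a floor of 3 counts. That floor may set the values of Fosb and Ankrd37. With the profile of barcodes with 100 to 500 counts, no ratio of a named gene moved by over 1.5-fold. With equal cluster weights Slpi went from 2.28 to 3.57 and Ddit3 from 2.99 to 3.85, and in cells of the same range of counts Mettl18 went from 2.08 to 1.46.

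**Figure D1:**
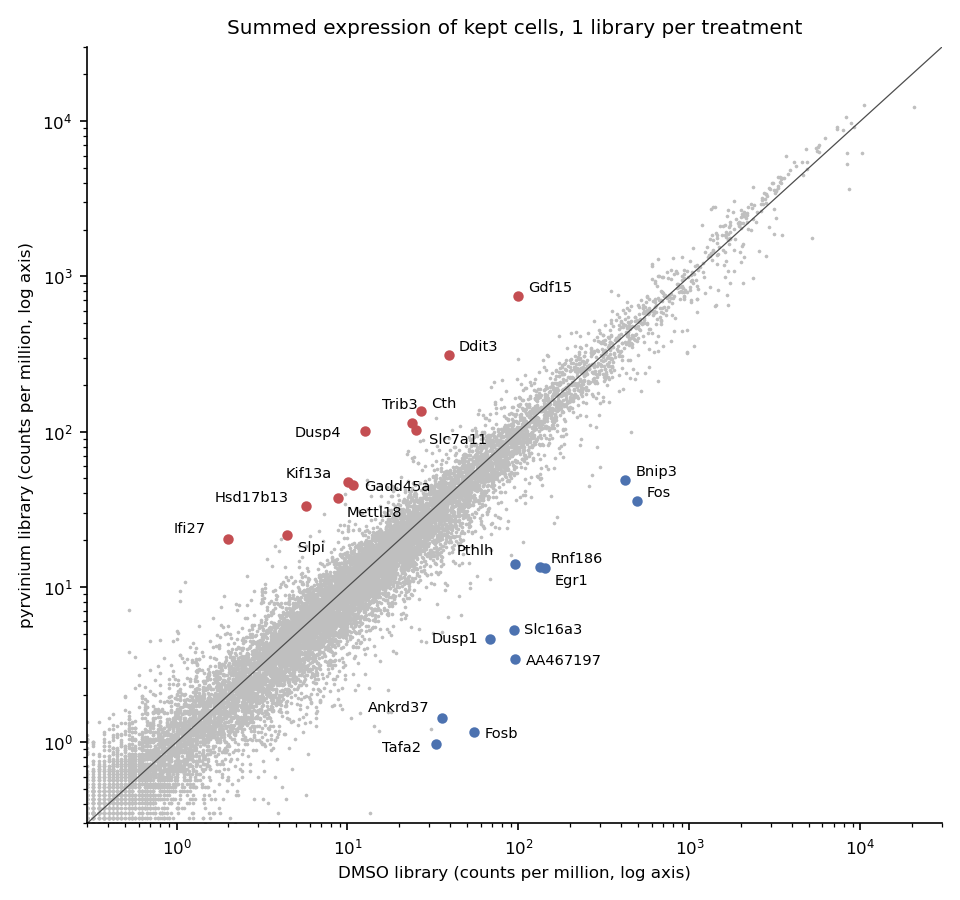
Summed expression of each gene in the kept cells of the DMSO library (horizontal, CPM, log axis) and the pyrvinium library (vertical, CPM, log axis). Grey points are genes, the line marks equal values, red points are the 12 genes with the highest and blue points 11 of the 12 with the lowest ratio; Gdf15 lies at 98.7 and 742 CPM and Fos at 491 and 35.9 CPM.

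Of the 24 measured genes of the integrated stress response, the program run by the transcription factor ATF4 when translation initiation is restrained, 18 were at least 1.5-fold higher with pyrvinium and 1 was lower. Their median log2 ratio was 0.88, above the middle 95% of matched random lists (-0.26 to 0.14). The exception was Atf3, which is also an immediate-early gene, at 162 CPM with DMSO and 25.7 CPM with pyrvinium. The unfolded protein response of the endoplasmic reticulum had a median of -0.12, at the 24.7th percentile of random lists, with 2 of 17 members at least 1.5-fold higher and 1 lower. Herpud1 was 1.74-fold higher and the chaperone gene Hspa5 was at 350 and 526 CPM, whereas Creld2 was 1.54-fold lower and Pdia3 1.44-fold lower. Interferon response genes were higher from a low base: 9 of 11 measured members were at least 1.5-fold higher and 1 was lower (median log2 ratio 1.25, random lists -0.47 to 0.24). Irf7 was at 1.13 CPM with DMSO and 10.7 CPM with pyrvinium, Ifi27 was 10.1-fold higher with 20.2 CPM, Oas1a was at 3.98 and 16.9, and the tetherin gene Bst2 at 146 and 311. Creld2 and Hspa5 were each under 1.5-fold in 4 alternatives, while within cluster 1 Hspa5 was at 211 and 675 CPM. Irf7 went from a log2 ratio of 3.25 to 2.66 in cells of the same range of counts.

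Hypoxia response genes, most of them direct targets of the transcription factor HIF, were lower with pyrvinium in 11 of 12 cases at the 1.5-fold limit and higher in 0. Their median log2 ratio was -1.52, against -0.35 to 0.21 for random lists. Besides Ankrd37 and Bnip3, the prolyl hydroxylase gene Egln3 was 5.73-fold lower, from 257 to 44.9 CPM, and the lipid droplet gene Hilpda 4.91-fold lower. Of 15 glycolysis genes, 12 were at least 1.5-fold lower and 0 higher, with a median of -0.95; in the S-phase-like cluster 2 described below the median was -0.22, with 3 of 15 lower. Among them the enolase gene Eno1 was 3.01-fold, Pfkl 2.68-fold and the lactate dehydrogenase gene Ldha 2.54-fold lower, in addition to Slc16a3. The spread over DMSO cells was wide. With every cell thinned to 5000 counts, DMSO cells held a median of 4 counts of the hypoxia list (quartiles 1 and 10, 90th percentile 20) and pyrvinium cells a median of 2 (quartiles 1 and 2, 90th percentile 4). The integrated stress response list gave 8 counts (quartiles 5 and 12) in DMSO cells and 23 (quartiles 15 and 30) in pyrvinium cells. Ddit3 was counted in 13.0% (11.4 to 14.7) of thinned DMSO cells and 58.2% (54.8 to 61.5) of pyrvinium cells, with 3.76% in the lowest cluster of the DMSO library, 32.3% in the lowest of the pyrvinium library, which is another cluster, and 29.7% and 85.9% without thinning. With 10% free RNA of barcodes with 10 to 100 counts subtracted, Egln3 went from a log2 ratio of -2.52 to -3.53 and Hilpda went to -3.15.

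**Figure D2:**
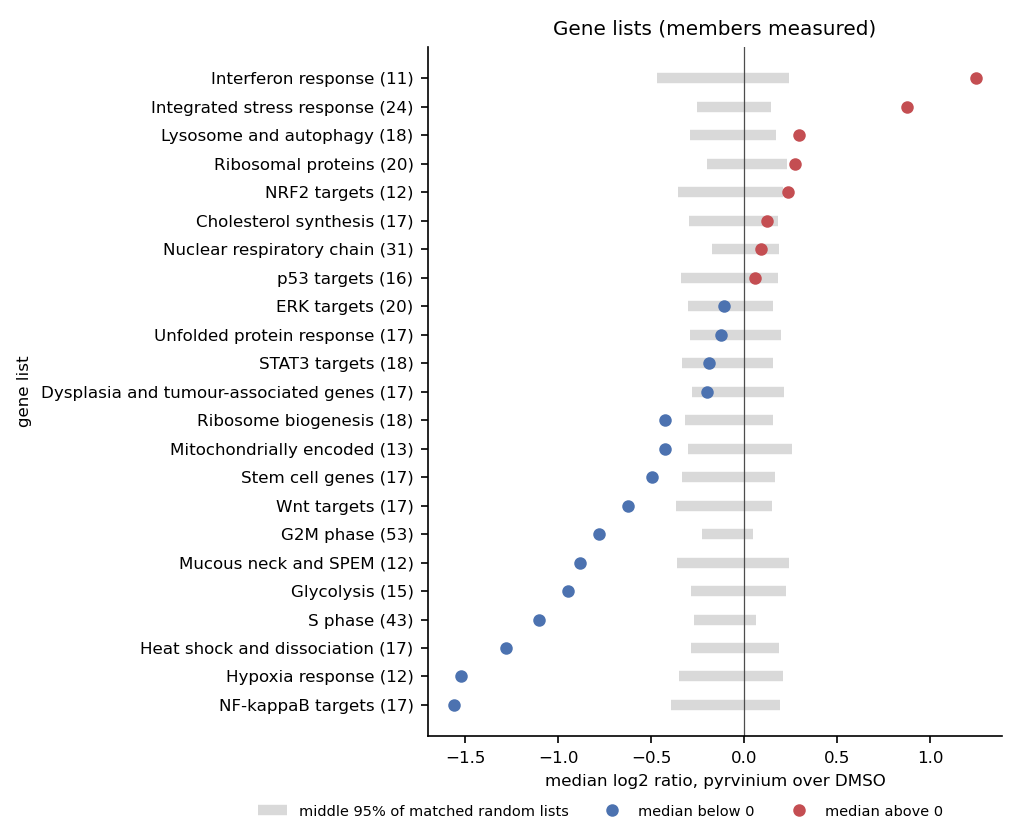
Median log2 ratio of pyrvinium over DMSO (horizontal axis) for each gene list with at least 10 measured members (vertical axis, number measured in brackets); grey bars are the middle 95% of 10000 random lists matched on expression, blue and red points are medians below and above 0. Hypoxia response lies at -1.52 and the integrated stress response at 0.88.

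Cell cycle genes were lower with pyrvinium. Of 43 S phase genes, 36 were at least 1.5-fold lower and 0 higher (median log2 ratio -1.11), and of 53 G2M genes 38 were lower and 1 higher (median -0.78). Random lists spanned -0.27 to 0.06 and -0.23 to 0.05. The flap endonuclease gene Fen1 was 4.92-fold lower, the replicative helicase gene Mcm5 3.68-fold, Chaf1b 3.67-fold and Uhrf1 3.38-fold, while among G2M genes Kif23 was 2.68-fold, Birc5 2.58-fold, Pimreg 2.53-fold and Kif11 2.53-fold lower. The proliferation markers Mki67 and Top2a differed less, from 23.5 to 14.3 CPM and from 25.3 to 15.7 CPM. At 5000 counts per cell, 10.3% of DMSO cells (interval 8.85 to 11.9) and 8.43% of pyrvinium cells (6.65 to 10.5) had an Mki67 count, a difference that was not detectable at this depth. For Top2a the shares were 10.5% (9.09 to 12.2) and 6.44% (4.89 to 8.30). No cell type that lacks Mki67 was identified here to serve as a background. Free RNA at an assumed 10% of counts would alone give shares of 1.45% (DMSO) and 0.99% (pyrvinium). The lowest share in a cluster of the DMSO library was 1.66%, in cluster 6. In the pyrvinium library it was 0% of 45 cells, in cluster 8. Neither of these clusters holds cells of the other library. Without thinning the Mki67 shares were 30.5% and 29.3%. Score-based calls put 32.4% of DMSO and 15.3% of pyrvinium cells in S and 26.0% and 15.8% in G2M; these calls also read free RNA, whose share per cell was not measured. With equal weights for the 3 clusters shared by the libraries, 22 S phase and 15 G2M genes were at least 1.5-fold lower. In that setting the log2 ratio went from -0.72 to -0.34 for Mki67, from -0.69 to -0.24 for Top2a and to -1.70 for Fen1. It went from -1.76 to -1.08 for Uhrf1 and from -1.34 to -0.74 for Pimreg. Cell cycle genes were not left out of the clustering, and such genes lead clusters 2 and 7. This setting is therefore no independent check of the cell cycle lists. In cells of the same range of counts Mki67 was at -0.36 and Top2a at -0.58, both under 1.5-fold.

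Wnt target genes were lower with pyrvinium. Of 17 genes, 11 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.62 (random lists -0.37 to 0.15). The direct target Sp5 was 4.59-fold lower, the feedback ubiquitin ligase gene Rnf43 3.59-fold, Ascl2 2.97-fold and the stem cell receptor gene Lgr5 2.63-fold lower. The stem cell list, which shares 8 genes with the Wnt list, had 8 of 17 members at least 1.5-fold lower and 0 higher (median -0.50). Axin2 was 2.57-fold and Lrig1 1.56-fold lower, and Sox9 was at 18.8 and 12.2 CPM; Lrig1 and Sox9 came under 1.5-fold when scaled otherwise. Over all cells the surface markers Cd44, Prom1 (CD133) and Alcam (CD166) lay close: Cd44 was at 112 CPM with DMSO and 101 CPM with pyrvinium, Prom1 at 126 and 115, and Alcam at 56.6 and 54.9. Within cluster 1, which holds the most cells of both libraries, they were lower with pyrvinium, Cd44 at 130.3 and 65.9 CPM, Prom1 at 115 and 69.6 and Alcam at 63.8 and 45.3. Cluster 7 had Cd44 at 101.01 and 73.6 and Prom1 at 129 and 94.9, and cluster 2 had log2 ratios of -0.12 and -0.15 for them. In thinned cells, Cd44 was counted in 40.7% (38.3 to 43.2) of DMSO and 38.1% (34.8 to 41.4) of pyrvinium cells. Prom1 was counted in 43.5% (41.1 to 46.0) and 38.1% (34.8 to 41.4). Its shares were 34.9% and 28.9% in the lowest cluster of each library and 81.7% and 85.1% without thinning. Cd44 and Prom1 were counted together in 18.6% and 17.0%, and Alcam in 23.8% and 24.2%. The lowest cluster of each library, not the same cluster in both, had 26.1% and 29.8% for Cd44 and 17.0% and 13.3% for Alcam, and without thinning the shares were 78.7% and 86.8% for Cd44, 64.6% and 77.6% for Alcam and 65.7% and 76.6% for Cd44 with Prom1. Lgr5 was counted in 11.5% (9.96 to 13.1) of DMSO cells and 3.16% (2.09 to 4.57) of pyrvinium cells; the lowest cluster of each library had 6.64% and 2.18%, and without thinning the shares were 33.9% and 24.1%. The number of stem cell genes at least 1.5-fold lower was 5 when scaled without mitochondrial and ribosomal genes or by the median of ratios, 4 in cells of the same range of counts and 10 with equal cluster weights. Within clusters 1, 2 and 7 it was 11, 5 and 10 of 17, with medians of -0.94, -0.51 and -0.99. In cells of the same range of counts 7 Wnt targets were lower. Sp5 went from a log2 ratio of -2.20 to -5.77 with free RNA of barcodes with 10 to 100 counts subtracted and to -3.14 with equal cluster weights, which put Lgr5 at -2.04 instead of -1.39.

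**Figure D3:**
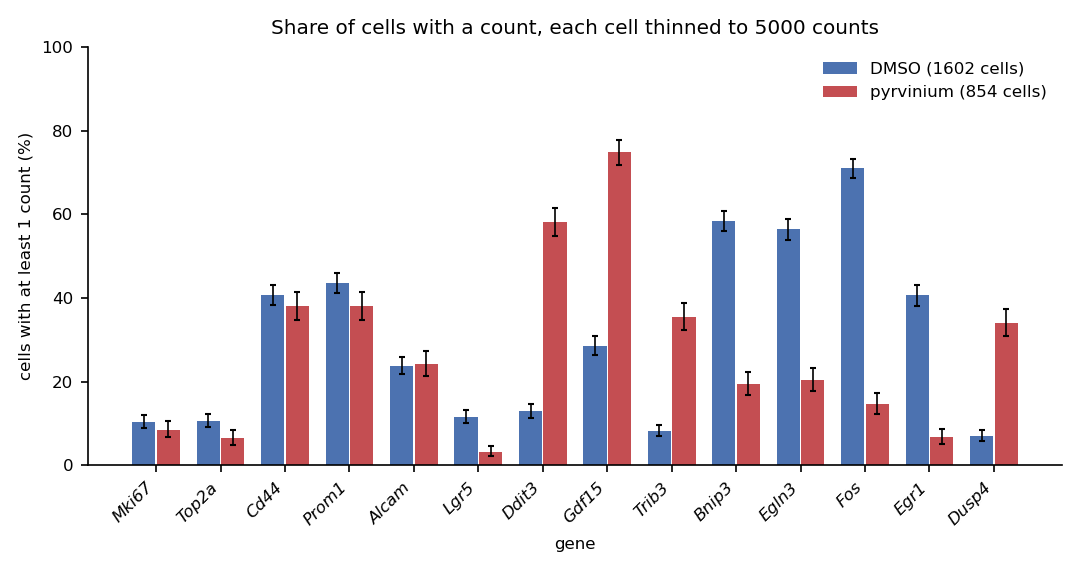
Share of cells with at least 1 count of a gene (vertical axis, %) in the DMSO library (blue, 1602 cells) and the pyrvinium library (red, 854 cells), each cell thinned to 5000 counts; whiskers are exact binomial 95% intervals. Cd44 lies at 40.7% and 38.1%, Lgr5 at 11.5% and 3.16%, and Ddit3 at 13.0% and 58.2%.

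The series is titled after suppression of MEK/ERK and STAT3 signalling. Signalling itself was not measured here, and RNA of target genes at 1 day does not stand for it. Transcripts that these pathways control were mixed. The 20 ERK targets had a median log2 ratio of -0.11, at the 37.2th percentile of random lists, with 6 members at least 1.5-fold lower and 1 higher. Within clusters 1, 2 and 7 their medians were -0.34, -0.20 and -0.33. Fos, Egr1 and Myc were lower, Myc from 66.6 to 30.6 CPM, and Dusp4 was higher. The widely used ERK readouts Dusp6 (25.1 and 25.3 CPM), Etv5 (25.5 and 27.3), Spry4 (2.35 and 2.59) and Ccnd1 (268 and 241) lay close together, and Etv4 had a log2 ratio of 0.32. The STAT3 list had 8 of 18 members at least 1.5-fold lower and 4 higher, a median of -0.19 and the 17.6th percentile. Its medians within clusters 1, 2 and 7 were -0.08, -0.56 and -0.30. Reg3g, an antimicrobial lectin gene, was 3.26-fold lower and the adhesion molecule gene Icam1 3.06-fold lower, whereas the lipocalin gene Lcn2 was 3.76-fold higher and Hif1a 3.21-fold higher. Socs3, the feedback inhibitor of STAT3, was at 14.0 and 11.8 CPM and Stat3 at 22.9 and 20.8. Lcn2 went from a log2 ratio of 1.91 to 3.03 with equal cluster weights and to 3.10 in cells of the same range of counts, Reg3g from -1.70 to -2.32 with equal cluster weights, and Spry4 from 0.14 to 0.82 with free RNA of barcodes with 10 to 100 counts subtracted.

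NF-kappaB targets were lower in 11 of 17 cases and higher in 1, with a median log2 ratio of -1.56 (random lists -0.39 to 0.19). The chemokine genes Cxcl5 and Cxcl1 were 7.33-fold and 6.47-fold lower, the inhibitor gene Nfkbia 5.91-fold and Tnfaip3 3.44-fold. With free RNA of barcodes with 10 to 100 counts subtracted, the log2 ratio went from -2.87 to -6.90 for Cxcl5, from -2.69 to -4.96 for Cxcl1 and from -2.56 to -3.58 for Nfkbia. The value of -6.90 may be set by the floor of 3 counts. Equal cluster weights put Cxcl5 at -4.77. The list of heat shock and dissociation genes, which report how cells fared during preparation, had 12 of 17 members at least 1.5-fold lower and 3 higher (median -1.28). Fosb, Dusp1, Fos and Egr1 are members of this list and were lower, as given above. Immediate-early genes were not listed or counted apart from it.

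The Epithelial list had 3 of 8 members at least 1.5-fold lower and 0 higher (median -0.36, and -0.43, -0.01 and -0.25 within clusters 1, 2 and 7); Krt19 was at 2060 CPM with DMSO and 906 CPM with pyrvinium, Krt8 at 2014 and 1237, Krt18 at 3218 and 2375, and Elf3 at 181 and 103. Dysplasia and tumour-associated genes had a median of -0.20 within the random range, with 4 of 17 lower and 2 higher. Within cluster 1 the median was -0.08, with 5 of 17 lower and 2 higher. It was 0.11 within cluster 2 and 0.38 within cluster 7, where 7 of 15 members were higher and 1 was lower, and 0.00 with equal cluster weights. Over all cells Lgals3 was 2.17-fold and Anxa1 1.96-fold lower, and Lcn2 was higher. With equal cluster weights Lgals3 (log2 ratio -0.54), Elf3 (-0.39), Krt8 (-0.53) and Glipr1 (-0.58) came under 1.5-fold. Genes of mucous neck cells and of spasmolytic polypeptide-expressing metaplasia (SPEM) were lower in 7 of 12 cases and higher in 1 (median -0.88, random lists -0.36 to 0.24), and their medians were -0.59, -0.48 and -0.64 within clusters 1, 2 and 7. Agr2 was 2.85-fold, Clu 1.88-fold and Glipr1 1.81-fold lower, but Wfdc2 was 1.60-fold higher; Tff2 was at 30.2 and 33.7 CPM and Muc6 at 3.88 and 1.84, a log2 ratio of -1.08 that was -0.53 with free RNA of barcodes with 10 to 100 counts subtracted and -1.72 at the threshold of 1000 counts. Surface mucous genes had a median of -0.17 with 1 of 8 members lower, Tff1 being at 333 and 404 CPM, Ctse at 76.8 and 60.4, Psca at 152 and 137 and Pla2g10 at 14.3 and 12.5. Muc5ac had 0 counts with DMSO, which allows at most 0.0923 CPM, and 1 count with pyrvinium. Of 8 measured intestinal genes 3 were lower (median -0.52), and within clusters 1, 2 and 7 it was 6 of 7, 4 of 7 and 3 of 4 (medians -1.07, -0.66 and -0.78). Over all cells Spink4 was 3.35-fold and Lgals4 2.06-fold lower, Vil1 was at 28.9 and 20.3 CPM and Tff3 at 13.4 and 10.2, and Cdx2 had 1 count with DMSO and 0 with pyrvinium. The log2 ratio of Spink4 went from -1.74 to -0.28, under 1.5-fold, in cells of the same range of counts and to -3.75 with equal cluster weights. Squamous genes had 4 of 6 members lower (median -1.22), with Krt4 at 19.3 and 3.78 CPM and Sprr1a at 37.7 and 24.3. Their median was -0.44 within cluster 1 and -0.02 within cluster 2, where 2 members were measured. In cluster 7 the 1 measured member was higher, at a log2 ratio of 2.44. Sprr1a turned direction with equal cluster weights, from a log2 ratio of -0.63 to 0.97, and Krt4 went from -2.35 to -3.21 in cells of the same range of counts.

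Further lists held markers of other lineages. The 8 chief cell genes summed to 13.5 CPM with DMSO and 5.70 with pyrvinium. Of them 3 were measured and all 3 were lower (median -1.51), but over members with at least 1 count in each library the median was -0.59. The 3 measured parietal cell genes had a median of -0.07 with 1 lower, which the alternatives moved between -1.09 and 0.22; Slc9a4 was at 19.2 and 9.47 CPM and Clic6 at 11.3 and 12.1. Tuft cell genes had a median of 0.49 with 1 of 7 members at least 1.5-fold higher and 0 lower, and Pou2f3 was at 79.7 and 93.6 CPM, Avil at 23.7 and 33.3 and Ltc4s at 23.4 and 24.9. Equal cluster weights put Avil at a log2 ratio of 1.16 instead of 0.49. The fibroblast, immune, erythroid and enteroendocrine lists each summed to under 4 CPM in either library, with 2, 1, 0 and 2 members measured; 0 fibroblast members and 1 immune and 1 enteroendocrine member were at least 1.5-fold higher. Of the endothelial list, 4 members were measured (median 0.15, 1 higher; -0.73 with free RNA of barcodes with 10 to 100 counts subtracted), and Cdh5 was at 41.7 and 56.5 CPM.

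Clustering gave 8 clusters, of which 5 drew at least 85% of their cells from 1 library when the libraries were weighted equally. Such a cluster may be the library and not a cell type, so cluster sizes are not compared. The 3 clusters with at least 30 cells of each library allow a comparison within them. Because of the z-scoring within each library, cells that share a cluster need not be of the same type. Cluster 2 was S-phase-like (led by Mcm7, Asf1b and Fen1, with Tyms and Mcm5), cluster 7 was G2M-like (led by Kif22 and Dlgap5, with Ckap2l, Kif2c and Cdc20), and cluster 1, led by Cnfn, Ly6c1 and Ptgs2, was not named. Integrated stress response genes were higher with pyrvinium in each, with median log2 ratios of 0.93 in cluster 1, 1.59 in cluster 2 and 1.32 in cluster 7. Within these clusters Ddit3 went from 20.3 to 476 CPM, from 8.02 to 69.6 CPM and from 38.9 to 425 CPM. Hypoxia response genes had medians of -1.50 in cluster 1 and -1.15 in cluster 7 but -0.26 in cluster 2, where 3 of 12 members were at least 1.5-fold lower and 1 was higher. In that cluster Bnip3 was at 110 CPM with DMSO, against 421 in cluster 1 and 508 in cluster 7. Egln3 was at 97.8 and 75.6 CPM in cluster 2, Rnf186 at 25.7 and 12.1, and Mettl18 at 7.61 and 7.56, so these genes differed less there than over all cells. Interferon response genes had medians of 2.10, 0.49 and 1.42, NF-kappaB targets -1.59 in cluster 1 and -1.84 in cluster 7, with 9 of 12 members lower in cluster 2, and S phase genes -0.90, -0.91 and -0.27. Sox9 within cluster 7 was at 19.7 and 3.89 CPM. Wnt targets had medians of -0.94, -0.56 and -1.39. G2M genes had medians of -0.76, -0.23 and -0.52, and Mki67 within cluster 7 was at 56.7 CPM with DMSO and 44.9 CPM with pyrvinium. Because cell cycle genes took part in the clustering, ratios of the S phase and G2M lists within clusters 2 and 7 are no independent check. Cluster 2 held 41 pyrvinium cells and cluster 7 held 74.

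**Figure D4:**
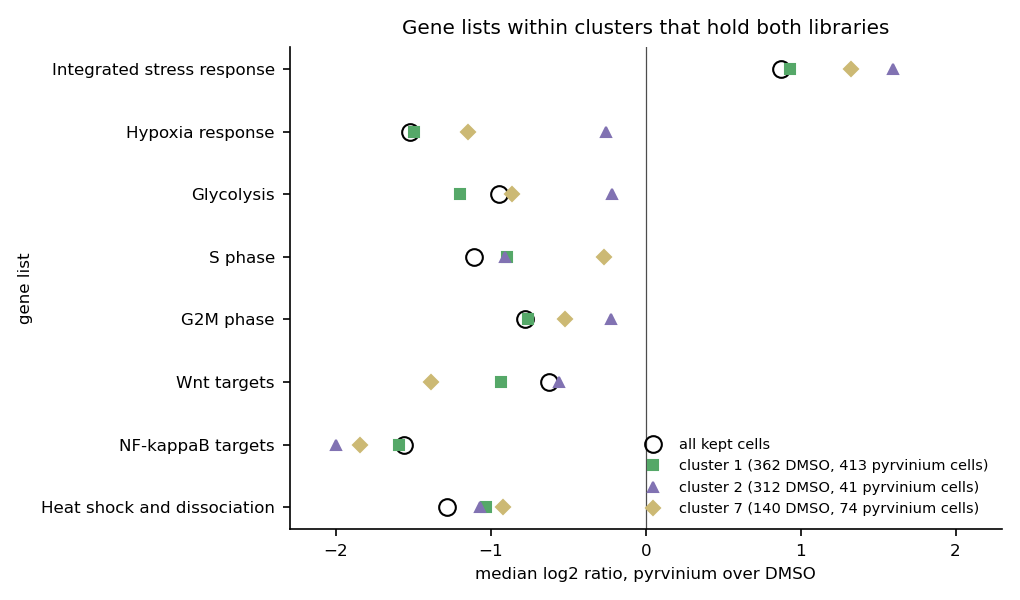
Median log2 ratio of pyrvinium over DMSO (horizontal axis) for 8 gene lists (vertical axis), over all kept cells (open circles) and within cluster 1 (squares), cluster 2 (triangles) and cluster 7 (diamonds). The integrated stress response lies above 0 in each, and the hypoxia response lies at -1.50, -0.26 and -1.15.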

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

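The barcodes not kept as cells were not part of the comparison of cells. Those with 100 to 500 counts were taken above as free RNA, which may come from the same cells. They are therefore no independent check of the results in cells. Among lists with at least 3 measured members, 2 had a median at least 1.5-fold higher with pyrvinium in barcodes with 100 to 500 counts and at least 3 members that were higher. The integrated stress response had a median log2 ratio of 0.85 there, and its members summed to 2932 CPM with DMSO and 5897 CPM with pyrvinium. Interferon response genes had a median of 1.40, and summed to 139 and 328 CPM. In the same barcodes Gdf15 was at 100.4 and 747 CPM and Ddit3 at 57.4 and 371 CPM. Other lists lay nearer to 0 on the higher side, such as NRF2 targets at 0.26 and ribosomal proteins at 0.23, or had a single enteroendocrine gene measured (3.96). Hypoxia response genes were lower there with a median of -1.90, heat shock and dissociation genes with -1.47 and glycolysis genes with -1.05.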

How the results depend on the processing

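Choices marked in the methods as added after seeing the data are the free RNA profile of 100 to 500 counts and the cells of the same range of counts. Of the 169 recomputed counts of list members, 163 stayed within 1.5 times the reported one; the counts of hypoxia response (11) and heat shock and dissociation genes (12) did not move in any of the 13 alternatives, and those of the integrated stress response spanned 17 to 21, glycolysis 10 to 13 and NF-kappaB targets 10 to 11. Equal cluster weights use 3 clusters and give the cycling clusters more weight. With them, 22 rather than 36 S phase genes and 15 rather than 38 G2M genes were at least 1.5-fold lower. Cell cycle genes took part in the clustering, so that setting is no independent check of these lists. Sprr1a turned from a log2 ratio of -0.63 to 0.97 with equal cluster weights, and the cause was not tested for Sprr1a. In cells of the same range of counts (978 DMSO and 515 pyrvinium cells), 7 rather than 11 Wnt targets and 4 rather than 8 stem cell genes were lower. Scaling without mitochondrial and ribosomal genes, or by the median of ratios, gave 5 and 5 stem cell genes, by construction of a shift of 0.07 and 0.09 in all ratios.

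The threshold set the number of cells: at least 1000 counts gave 4114 DMSO and 3051 pyrvinium cells, and at least 3000 counts 2761 and 1725, against 1602 and 854. Thinned to 1000 counts, cells of the 1000-count threshold had an Mki67 count in 2.92% (DMSO) and 2.06% (pyrvinium) and a Top2a count in 3.28% and 1.74%. The lower threshold changed the barcodes and the depth together, so the effect of each was not separated there. In the 1602 and 854 cells of the main setting, the shares without thinning were 30.5% and 29.3% for Mki67 and 31.1% and 31.03% for Top2a. Of 1632 recomputed ratios of named genes, 1166 stayed within the counting interval, 465 moved and 1, that of Sprr1a, changed sign among those at least 1.5-fold apart. A total of 40 ratios differed by over 1.5-fold from the reported ones, 18 with free RNA of barcodes with 10 to 100 counts subtracted and 15 with equal cluster weights, and those of the genes reported are given beside them. For 16 genes at least 1 alternative came under 1.5-fold: Creld2, Elf3, Glipr1, Hspa5, Insig1, Krt8, Lgals3, Lrig1, Mki67, Muc6, Sox9, Spink4, Sprr1a, Top2a, Trp53inp1 and Uqcrq. Of 416 list medians 321 stayed within the counting interval, 95 moved and 0 of at least 1.5-fold changed sign; the cause was not tested. Z-scoring over both libraries left 0 clusters with at least 30 cells of each, against 3.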

Other observations

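Tests of the mix of clusters, of clusters left out, of dissociation and of the number of libraries were chosen after the results were seen. Further gene groups differed between the libraries. Lysosome and autophagy genes had a median log2 ratio of 0.30 (random lists -0.29 to 0.17), with 4 of 18 members at least 1.5-fold higher and 1 lower. The autophagy receptor gene Sqstm1 was at 79.7 CPM with DMSO and 214 CPM with pyrvinium, the hexosaminidase gene Hexa at 22.9 and 41.6, Gabarapl1 at 19.9 and 36.1, and the cathepsin gene Ctsl at 145 and 250. NRF2 targets had a median of 0.23 over all cells, with 2 of 12 members higher and 0 lower, and medians of 0.51, 0.62 and 0.52 within clusters 1, 2 and 7, with 5, 6 and 6 members higher; Nqo1 was 1.91-fold higher, Abcc1 1.42-fold and Osgin1 1.40-fold, and Slc7a11 is also counted in the integrated stress response. Ribosome biogenesis genes were lower in 8 of 18 cases and higher in 0 (median -0.43), and in 15 of 18 within cluster 2 and 1 of 18 within cluster 7, with Dkc1 2.13-fold, Nolc1 2.01-fold, Nop56 1.98-fold and Nop58 1.80-fold lower. The ribosomal protein list lay on the other side of 0, with a median of 0.27 and 0 of 20 members past 1.5-fold; Rplp1 was 1.37-fold, Rps14 1.30-fold, Rps2 1.29-fold and Rplp0 1.26-fold higher.

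The p53 targets had a median of 0.06, with 1 of 16 members higher and 1 lower. Within clusters 1, 2 and 7, 4 of 16, 1 of 16 and 5 of 14 members were higher and 0, 1 and 1 lower. The medians there were -0.01, -0.21 and 0.52. Over all cells Trp53inp1 was 1.61-fold (under 1.5-fold in 4 alternatives) and Tnfrsf10b 1.37-fold higher, Btg2 was 1.78-fold and Pmaip1 1.46-fold lower (log2 ratio -0.54, but 0.19 with equal cluster weights), and Cdkn1a was at 839 and 1083 CPM. Cholesterol synthesis genes had a median of 0.12 with 2 of 17 lower and 0 higher (Insig1 1.58-fold lower, but under 1.5-fold in 3 alternatives), and a median of 0.43 within cluster 2, where 6 members were higher and 1 was lower, while Sc5d was 1.32-fold lower and Hmgcs1 1.31-fold higher. Nuclear genes of the respiratory chain were neither higher nor lower by this rule in 30 of 31 cases (median 0.09); the exception was Uqcrq, 1.60-fold higher but under 1.5-fold with equal cluster weights and in cells of the same range of counts, and Ndufs7 was 1.33-fold and Ndufa2 1.23-fold higher and Ndufa4 1.20-fold lower. Of 6 measured genes of mesenchymal transition 1 was lower (median -0.11, and -0.75 over members with at least 1 count in each library), and Fn1 was at 29.8 and 24.8 CPM. Hif1a was 3.21-fold higher in the pyrvinium library, in which the hypoxia response list was lower.

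Hypoxia response genes were low in the pyrvinium library. Cluster 6, led by Cited1, Lims2 and Ly6m, held 241 cells of the DMSO library and 0 of the pyrvinium library. Cluster 6 alone is not the whole account: without it the hypoxia median went from -1.52 to -0.90, with 11 of 12 members still lower. Clusters 3 and 4, with 266 DMSO cells each and 14 and 13 pyrvinium cells, were not left out. Within clusters 1, 2 and 7, which hold both libraries, the medians were -1.50, -0.26 and -1.15. Other cells found mainly in the DMSO library were therefore not excluded as a part of the cause. A difference in counts per cell is argued against by the median of -1.51 in cells of the same range of counts. A difference between the cultures other than the drug, such as their density or oxygen supply, cannot be told apart from the treatment with 1 library per group, and either may account for the pattern.

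The lists of heat shock and dissociation genes and of NF-kappaB targets were low in the pyrvinium library. A different mix of the clusters with at least 30 cells of each library would leave them level within these clusters. The median nearest 0 there, that of the heat shock and dissociation list in cluster 7, was -0.92. The other clusters could not be compared. Clustering used values z-scored within each library, so cells of a shared cluster need not be of the same type. A different mix of cell types was therefore not excluded. A stronger dissociation response in the DMSO cells would raise heat shock protein genes there too. These went both ways, with a median log2 ratio of 0.44 over 6 genes, Hspa1a at 2.01 and Dnajb1 at -1.59, so dissociation and treatment cannot be told apart and both remain candidate explanations.

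Mitochondrially encoded transcripts moved apart. The list had a median of -0.43 (-0.77, -0.49 and -1.10 within clusters 1, 2 and 7), with 6 of 13 members lower and 2 higher; mt-Atp6 was 2.35-fold, mt-Cytb 2.09-fold and mt-Nd4 1.96-fold lower, but mt-Co1 was 2.02-fold higher, with an uncertain level in cells because barcodes with 100 to 500 counts held more of it (665 and 807 CPM) than cells (218 and 439 CPM). The gap between mt-Co1 and mt-Atp6 was 2.25 on the log2 scale, and 1.89 at the threshold of 1000 counts, where the log2 ratio of mt-Co1 was 0.62 instead of 1.01. It was 2.52 after 10% of the counts, an assumed share, was subtracted as free RNA in the profile of these barcodes. With the profile of barcodes with 10 to 100 counts it was 2.20, and in cells of the same range of counts 2.32. These values argue against free RNA and counts per cell as the whole cause, for free RNA only at that share. The list median was -0.85 with free RNA of barcodes with 10 to 100 counts subtracted and -0.25 in cells of the same range of counts. Counts shared with nuclear copies cannot be told apart, because the 16 nuclear genes sharing sequence with these transcripts are not among the genes counted and the gap with them added was again 2.25; an effect of pyrvinium on mitochondrial transcripts may be followed up as a hypothesis.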
